A study of Rattus norvegicus with 4 samples.

How the data were processed

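RNA-seq was carried out on 4 libraries of the rat CG4 line, 2 transduced with a GFP retrovirus (ctrl) and 2 with a Phf8 and GFP retrovirus (Phf8oe), read as pairs of 150 bases per the labels. RNA was taken after 3 days of differentiation, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 2.20, Trimmomatic 0.36, STAR 2.5.2b and DESeq2 were used with the rat builds rn6 and Rnor_6.0. The gene counter, the annotation release, the use of strand and the filter that set which genes are listed are not given in the sources used here.

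The deposited signal is a normalized count per gene and library, although the labels call it raw. This was read from the values. In Phf8oe replicate 2, 85 of 85 whole numbers that scaled and rounded reads would skip between 10 and 300 were absent, and in ctrl replicate 2, 5 of 5. In ctrl replicate 1 and Phf8oe replicate 1, whole numbers where a pair of read counts would coincide occurred 1.95 and 2.09 times as often as their neighbours. The value of 1 read was 0.8445, 1.0176, 0.9548 and 1.4159 in ctrl replicates 1 and 2 and Phf8oe replicates 1 and 2. Median ratios of the libraries to the gene-wise geometric mean lay between 1.001 and 1.003, as median-of-ratios scaling gives. Reads assigned to the listed genes were estimated as about 47800000, 39300000, 43100000 and 28400000, against deposited totals of 40336248, 39945215, 41149255 and 40260658. The method recovered 4 simulated steps to within 0.0174%. The 4 sample files matched their columns of the series table exactly, and no gene had a mean under 6. Replicates differed by more than counting error (chi-square per degree of freedom 20.9 in ctrl and 34.2 in Phf8oe), so each was counted as 1 sample.

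A quasi-likelihood count model had been planned, but such a model needs unscaled counts. The values were tested instead with limma 3.58.1 in R 4.3.3 on log2(value + 1), so fold changes of low genes are understated. Genes with a value of at least 10 in at least 2 libraries were kept, leaving 14368 of 14410. The model had the group as its only term, with empirical Bayes variance moderation that followed the mean level and was robust to outlying genes, which left 2 residual and a median of 6.99 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Group values are means with SDs over 2 libraries.

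Before the data were examined, 25 gene lists, the group comparison and the rule for naming genes were fixed. Named were Phf8, the 12 genes that rose most and the 12 that fell most, and up to 4 members of each list. The first were taken among genes past the threshold with non-overlapping groups and a mean log2 CPM of at least 1, leaving out symbols starting with LOC, RGD, MGC or Rn. List members were those past the threshold with the smallest p, or the 2 most abundant where none passed. Some genes that the rule takes are not reported here. Other genes named were chosen after their values were seen. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. With an estimated correlation, camera rests on the 2 residual degrees of freedom and so had little power here. Lists of ERK pathway activity, mitochondrially encoded genes and very long messenger RNAs were added after the data were examined.

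The procedure was tested on simulated data: 10 sets of reads drawn for the real genes and depths, with 200 genes changed, scaled and rounded as deposited, of which between 14288 and 14308 genes were tested. For the comparison of Phf8oe with ctrl, 95.1% of 4-fold and 78.3% of 2-fold changes were called, none with the wrong sign, and 12.4% of the calls were false against the nominal 5%. Without robust moderation the shares were 93.9%, 73.6% and 8.66%. The adjusted p-values are thus somewhat too small under these simulated conditions. Changes under 2-fold were not simulated, so the shares called and the lack of wrong signs do not carry over to them. Of the 1098 genes called in the data, 325 changed at least 2-fold. With no list changed on purpose, 1 of the 25 lists passed camera at the preset correlation in 1 simulated set, which held the 200 changed genes. Genes were drawn independently of each other, so this cannot show how the preset correlation performs when genes are correlated.

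Alternatives covered limma-voom on estimated reads, other scalings, filters and pseudocounts, variance moderation, replicate numbers as a block, a test against a 1.5-fold change and leaving out each library. Gene symbols were placed on the GRCr8 assembly of RefSeq to learn which genes neighbour or overlap. Of the 14368 tested genes 12093 were placed, and 11 of 98 placed named genes overlapped another tested gene. That assembly is not the build used for the counts, so its positions are not given. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.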

Results

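Gene expression was measured by RNA-seq in CG4 cells, a rat glial progenitor line that can be driven to form oligodendrocytes, the myelin-forming cells of the central nervous system. The cells had been transduced with a retrovirus carrying GFP alone (ctrl) or Phf8 together with GFP (Phf8oe), sorted for GFP, expanded and kept under differentiating conditions for 3 days. Each group held 2 biological replicates, and the deposited table gave normalized counts for 14410 genes. These summed to 40336248 in ctrl replicate 1, 39945215 in ctrl replicate 2, 41149255 in Phf8oe replicate 1 and 40260658 in Phf8oe replicate 2. The spacing of the values placed the reads behind them at about 47800000, 39300000, 43100000 and 28400000 in the same order. Nothing in the labels says whether the replicates came from separate transductions, so the adjusted p-values measure the spread between these cultures or preparations only.

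The comparison of Phf8oe with ctrl asks which genes respond in differentiating oligodendroglial cells to a raised level of Phf8, a histone lysine demethylase. Of 31 measured genes of myelin and the mature oligodendrocyte, 11 rose in Phf8oe and 20 did not pass the test (camera adjusted p for the list = 5.4e-08 with a preset and 0.552 with an estimated correlation). Mbp, a major myelin protein, rose 1.81-fold. Of 31 immediate early genes, 13 fell, Spry2 by 2.36-fold, and 18 did not pass (camera adjusted p = 4e-09 with a preset and 0.686 with an estimated correlation). Gfap, the intermediate filament protein of astrocytes, fell 5.48-fold, and Il33, an alarmin cytokine found in glial nuclei, fell 8.52-fold, and Pdgfra, the receptor that marks oligodendrocyte progenitors, fell 1.81-fold. Without ctrl replicate 1 the calls of Mbp, Gfap, Pdgfra and Spry2 were lost. In that fit the spread is measured between the Phf8oe libraries alone. With 1 library left out at a time, the log2 fold change of Mbp ranged from 0.79 to 0.93. The ranges were -2.88 to -2.03 for Gfap, -0.93 to -0.79 for Pdgfra and -1.33 to -1.14 for Spry2.

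The transduced gene was looked at first. Normalized counts of Phf8 were 2026 and 2205 in the ctrl libraries and 5650 and 10796 in the Phf8oe libraries. The log2 fold change was 1.89 (SE 0.35, n = 2 per group), or 3.69-fold, with a Benjamini-Hochberg adjusted p of 0.0631 in limma. Phf8 was therefore higher in both Phf8oe libraries than in both ctrl libraries but did not pass the threshold, the Phf8oe libraries differing from each other by 1.91-fold. Over the alternatives that tested Phf8, the limma adjusted p ranged from 2.98e-10 to 0.327; it was 0.0194 without robust variance moderation, 0.0313 with the replicate number as a block, 0.126 with crossed pairing and 0.119 with no variance trend. Leaving out a Phf8oe library removes the spread between them: without replicate 1 the log2 fold change was 2.35 (adjusted p = 2.98e-10), and without replicate 2 it was 1.42 (adjusted p = 1.24e-07). It was 1.82 without ctrl replicate 1 (adjusted p = 0.327) and 1.95 without ctrl replicate 2 (adjusted p = 0.177). The deposited value is the total for Phf8, and the species of the transduced sequence is not given in the sources used here.

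**Figure D1:**
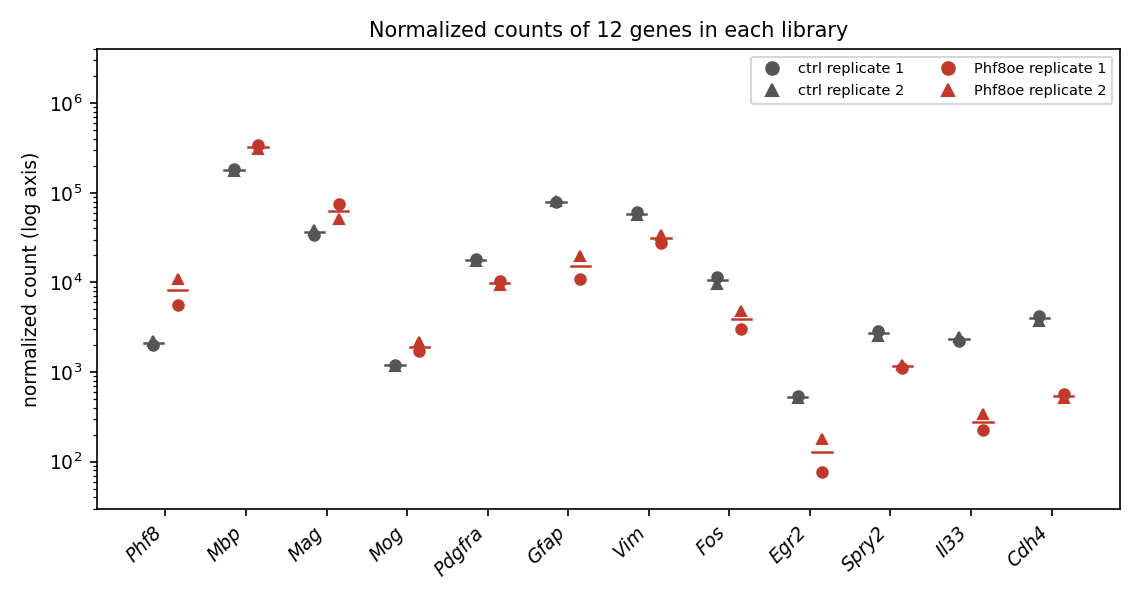
Normalized counts (log axis) of 12 genes in the 4 libraries, with ctrl in grey and Phf8oe in red; circles are replicate 1, triangles replicate 2 and short lines the group means. Phf8 lies at 5650 and 10796 in the Phf8oe libraries against 2026 and 2205 in the ctrl libraries, and Gfap at 10834 and 19613 against 79141 and 80736.

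Of 14368 genes tested, 1098 differed between the groups at a Benjamini-Hochberg adjusted p under 0.05 in limma, 430 of them higher and 668 lower in Phf8oe. A change of at least 2-fold was seen in 325 of these, 82 higher and 243 lower. The 4 libraries correlated across genes at r = 0.994 within ctrl, r = 0.989 within Phf8oe, and between 0.977 and 0.985 across the groups; genes are not independent replicates. In all 1098 genes the groups did not overlap, which held for 57.6% of all tested genes, against 33.3% by chance with 2 libraries per group. Leaving out a library leaves the spread to be measured in the other group alone. The SD of the log2 difference between replicates was 0.32 in ctrl and 0.41 in Phf8oe. The count rested on each library: it fell sharply without either ctrl library and rose without either Phf8oe library. It was 806 without robust moderation (256 higher, 550 lower) and 0 when the variance was not allowed to follow the expression level, and upper quartile scaling turned the split to 608 higher and 589 lower.

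Among the genes that rose most, Tmem178a went from 122 and 106 normalized counts in ctrl to 515 and 450 in Phf8oe (log2 fold change 2.07, SE 0.19, limma adjusted p = 0.00145). Ptgds, the prostaglandin D synthase of glia and meninges, rose 3.9-fold, from 123 ± 21.2 to 486 ± 121 (SD, n = 2). Lzts1 rose 3.28-fold, Nod1, an innate immune sensor of bacterial cell walls, 3.02-fold, and the phospholipase gene Pla2g3 2.9-fold. Tmem125, Bpifa1, Tle6, Lypd6, Lrp2 (an endocytic receptor) and Cyp46a1 (cholesterol 24-hydroxylase) rose between 2.5-fold and 2.85-fold.

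The smallest p of any gene belonged to Cdh4, encoding R-cadherin, which fell. Its normalized counts were 4251 and 3678 in ctrl and 573 and 514 in Phf8oe (log2 fold change -2.86, SE 0.12, limma adjusted p = 3.12e-05). Il33 fell from 2246 and 2451 to 223 and 338 (log2 fold change -3.09, SE 0.2, limma adjusted p = 0.000832). Kitlg, the ligand of the receptor Kit, fell 7.79-fold, the neuropeptide precursor gene Vgf 6.64-fold, the growth factor gene Fgf2 6.25-fold and the chemokine gene Cxcl14 5.86-fold. The adhesion genes Cadm3 and Nrxn3 were lower by 6.08-fold and 5.82-fold, and the potassium channel genes Kcnt1 and Kcna3 by 5.74-fold and 5.57-fold. Leaving out one library moved the log2 fold change of Nrxn3 between -3.13 and -1.95 and that of Ccdc103 between -4.03 and -2.73. Fgf2 overlaps Nudt6, which also fell (log2 fold change -1.36), and reads of overlapping genes may not be separable since the use of strand is not stated. FAM187A (752 and 381 against 37 and 52) and Ccdc103 (627 and 255 against 37 and 38) also fell; both overlap Eftud2 and neighbour Gfap in the GRCr8 assembly, and their values differed widely between the ctrl libraries.

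**Figure D2:**
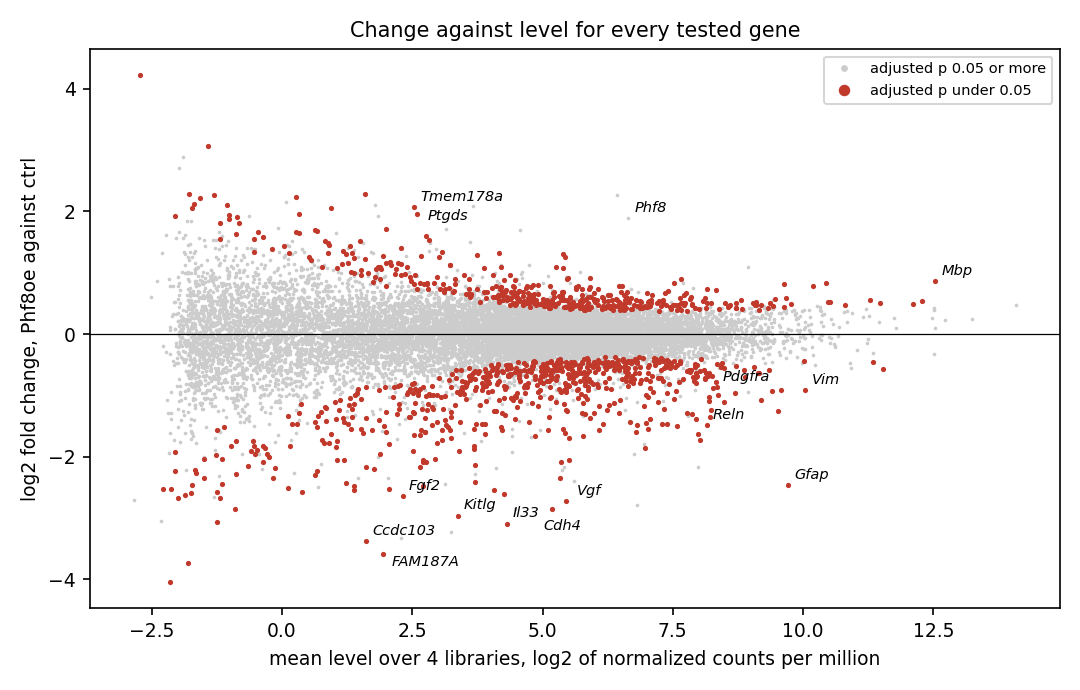
Log2 fold change (Phf8oe against ctrl) of each tested gene against its mean level over 4 libraries (log2 CPM from normalized counts); red points have a limma adjusted p under 0.05. Gfap stands out below at -2.46 and Mbp above at 0.86 among abundant genes, and Phf8 at 1.89 is not red.

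Of 31 measured genes of the list for myelin and the mature oligodendrocyte, 11 rose, none fell and 20 did not pass the test (15 rose when adjusted over the list alone). Mbp went from 184442 and 173338 normalized counts to 340486 and 308875, Gpr37 rose 2.18-fold and Plekhb1 1.59-fold. Mog rose 1.6-fold and Mag 1.71-fold, and Tmem125, Ppp1r14a, Tspan2 and Gal3st1 were also among the risers. Of all 31 genes, 27 lay higher and 4 lower. Some stood near no change: the log2 fold change was -0.01 for Cldn11 and Opalin, 0.02 for Aspa and 0.05 for Tf. These were picked after their values were seen. The list as a whole lay higher than other genes in limma's camera test with its preset correlation (median log2 fold change 0.44, adjusted p = 5.4e-08). With an estimated correlation the camera adjusted p was 0.552.

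Of 25 progenitor genes, 4 fell: Pdgfra from 18113 and 17240 to 10250 and 9286, Sox6 1.56-fold, Sox11 1.48-fold and the glutamate receptor gene Gria3 1.56-fold (9 fell and 1 rose adjusted over the list alone). The remaining 21 did not pass, and the list did not pass camera (adjusted p = 0.224), its median log2 fold change being 0.05 and its mean -0.08. The median was -0.31 with a minimum of 50 in both libraries of a group (adjusted p = 0.125), -0.2 without ctrl replicate 1 (adjusted p = 0.0959) and -0.27 without Phf8oe replicate 1, where the list passed (adjusted p = 0.0138). Among 32 transcription and chromatin regulators of the lineage, Zfp488 rose 1.52-fold and Sox6 and Nfatc2 fell, with the same number adjusted over the list alone, and the list did not pass camera (adjusted p = 0.264). Sox10 stood at a log2 fold change of 0.11 (SE 0.11) and Myrf at 0.11 (SE 0.13), neither past the threshold; these were picked after their values were seen.

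Of 25 cholesterol synthesis genes, 6 rose and none fell (12 rose adjusted over the list alone). Mvd rose 1.73-fold, Ebp 1.51-fold, Insig1, an inhibitor of sterol synthesis, 1.43-fold and Idi1 1.4-fold. The camera adjusted p was 1.58e-07 with the preset correlation and 0.686 with an estimated correlation. In fatty acid and sphingolipid synthesis, 2 of 28 genes rose (2 adjusted over the list alone): Srebf1, a regulator of lipid synthesis, 1.79-fold and Gal3st1, the sulfatide synthase, 1.55-fold. That list passed camera (adjusted p = 0.0242; adjusted p = 0.686 with an estimated correlation), but not without ctrl replicate 2 (0.253) or without Phf8oe replicate 1 (0.202).

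The immediate early response was the list that moved most by its median. Of 31 genes, 13 fell, none rose and 18 did not pass (20 fell adjusted over the list alone), with a median log2 fold change of -0.94. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, went from 2900 and 2551 to 1117 and 1192 (log2 fold change -1.24, SE 0.11, limma adjusted p = 0.00145). Arc fell 4.69-fold, Klf6 2.91-fold and Dusp6, a phosphatase acting on ERK, 1.86-fold. Fos fell from 11584 and 9626 to 3022 and 4774, and Fosl2, Fosl1, Fosb, Jun, Junb, Ier2, Egr2 and Egr3 fell too. The log2 fold change of Egr2 was -1.55 without Phf8oe replicate 1 and -2.77 without replicate 2, and its call was lost without either ctrl library (highest adjusted p = 0.282). The camera adjusted p was 4e-09, and 0.686 with an estimated correlation.

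In the S phase list 5 of 43 rose and none fell (6 rose adjusted over the list alone), including Pold1, the catalytic subunit of DNA polymerase delta, 1.45-fold, Ccne1 1.49-fold, Chaf1b 1.61-fold and E2f1 1.56-fold. In the list for G2 and mitosis 2 of 43 rose, Cdc20 and Birc5 by 1.48-fold each (2 adjusted over the list alone). Camera gave an adjusted p of 1.58e-07 for both lists, and 0.686 for both with an estimated correlation.

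Of 65 cytosolic ribosomal protein genes 17 rose and none fell (54 rose adjusted over the list alone), such as Rps20 1.55-fold, Rpl17 1.52-fold, Rpl35 1.43-fold and Rps23 1.41-fold. Reads of these genes can also fit their processed pseudogenes. In oxidative phosphorylation 3 of 36 rose, Ndufs7 1.53-fold, Ndufa2 1.42-fold and Ndufb10 1.36-fold (4 adjusted over the list alone), and in ribosome biogenesis none of 36 changed, with none adjusted over the list alone, where Ncl stood at a log2 fold change of -0.01 and Npm1 at 0.33. Camera gave adjusted p = 2.82e-18, 5.5e-07 and 0.0498 for these lists, each 0.686 with an estimated correlation. Ribosome biogenesis did not pass with limma-voom (0.0621), total scaling (0.074), the stricter filter (0.0537) or crossed pairing (0.0561), nor without ctrl replicate 2 (0.674) or without Phf8oe replicate 2 (0.614). Mitochondrial transcripts took 3.68% and 3.62% of the ctrl and 5.34% and 4.76% of the Phf8oe values. Very long messenger RNAs, a list of 54 measured genes drawn up after the data were examined, had a median log2 fold change of -0.25 (camera adjusted p = 2.27e-06, and adjusted p = 0.137 with an estimated correlation).

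Of 36 histone methylation regulators 6 fell and none rose (8 fell and 1 rose adjusted over the list alone), led by Kmt2a 1.67-fold, Kdm3a 1.45-fold, Kdm2a 1.4-fold and Setd1b 1.37-fold. Camera gave adjusted p = 0.00489, and adjusted p = 0.686 with an estimated correlation; several of these transcripts are long, and the very long messenger RNAs stood at -0.25 as above. In hypoxia and glycolysis 3 of 30 fell (4 adjusted over the list alone): Pfkfb4 1.81-fold, Kdm3a 1.45-fold and Ldha, lactate dehydrogenase A, 1.37-fold. That list passed camera (adjusted p = 0.00197; adjusted p = 0.686 with an estimated correlation), but not without ctrl replicate 2 (0.44).

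Markers of other cell types did not move in one direction. Of 19 astrocyte genes 4 fell, Gfap, Clu 2.57-fold, Vim 1.9-fold and Atp1b2 1.89-fold, while Aldh1l1, an astrocyte folate enzyme, rose from 9 and 10 to 32 and 44, and the glutamate transporter gene Slc1a3 rose 1.47-fold (6 fell and 3 rose adjusted over the list alone; camera adjusted p = 0.102, but 0.0368 with a minimum of 50 in both libraries of a group and 0.0278 without Phf8oe replicate 2). Clu overlaps Scara3, which also fell but had far fewer counts. Scara3 had a mean of 840 in ctrl and 378 in Phf8oe, against 19529 and 7585 for Clu. Of 22 neuronal genes Reln, an extracellular signalling protein, fell from 19228 and 19361 to 6947 and 6748, and Nefm fell 3.25-fold. Nrgn, a low gene, rose 3.77-fold, from 9 and 12 to 32 and 55 (5 neuronal genes fell and 3 rose adjusted over the list alone). Of the 22 neuronal genes 16 lay lower and 6 higher, with a median log2 fold change of -0.43. The neuronal list passed camera in the lower direction (adjusted p = 0.0344, and adjusted p = 0.686 with an estimated correlation). It did not pass without ctrl replicate 2 (median -0.39) or without Phf8oe replicate 2 (median -0.2). Of 16 fibroblast and pericyte genes Col1a1 fell 3.15-fold, Sparc 1.5-fold and Col5a1 1.35-fold and Postn rose 2.78-fold (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.291, and 0.0125 without Phf8oe replicate 2). Of 19 Schwann cell and neural crest genes 2 fell, Tfap2a and Egr2, and 1 rose (5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.385). None of 8 microglial genes changed, with none adjusted over the list alone (camera adjusted p = 0.615), and Cd68 had a log2 fold change of 0.03.

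The remaining lists held 1 to 5 changed genes each and did not pass camera, except under the alternatives given. Rxrg, a retinoid X receptor expressed in the oligodendrocyte lineage, fell 3.02-fold, alone of 18 retinoic acid response genes (1 adjusted over the list alone; adjusted p = 0.185, and 0.00576 without Phf8oe replicate 2). In the Notch, BMP and Wnt list of 30, Lef1 and Jag1 fell 1.88-fold and 1.92-fold and Lgr5 and Bmp4 rose 1.67-fold and 1.59-fold (4 fell and 3 rose adjusted over the list alone; adjusted p = 0.487). Among 27 p53 targets and cell cycle exit genes Gadd45a rose 1.67-fold, Plk2 fell 1.7-fold and Cdkn1c, an inhibitor of cell division, fell 1.48-fold (3 fell and 2 rose adjusted over the list alone; adjusted p = 0.487). Of 33 stress response genes Psat1, Mthfd2, Phgdh and Creld2 rose, the first 3 serving serine and folate metabolism, and Vldlr fell (8 rose and 2 fell adjusted over the list alone; adjusted p = 0.175, and 0.0179 without ctrl replicate 1). Among 38 actin cytoskeleton genes Pak1 fell 1.91-fold, Gsn fell 1.36-fold and Rnd2 rose 1.31-fold (6 fell and 4 rose adjusted over the list alone; adjusted p = 0.628). Psmb8 and Mx2 rose among 34 interferon genes (2 adjusted over the list alone; adjusted p = 0.487), and H2afx rose 1.41-fold among 39 repair genes (1 adjusted over the list alone; adjusted p = 0.0649, but 0.0458 with the replicate block, 0.0226 without ctrl replicate 2 and 0.0322 without Phf8oe replicate 1).

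**Figure D3:**
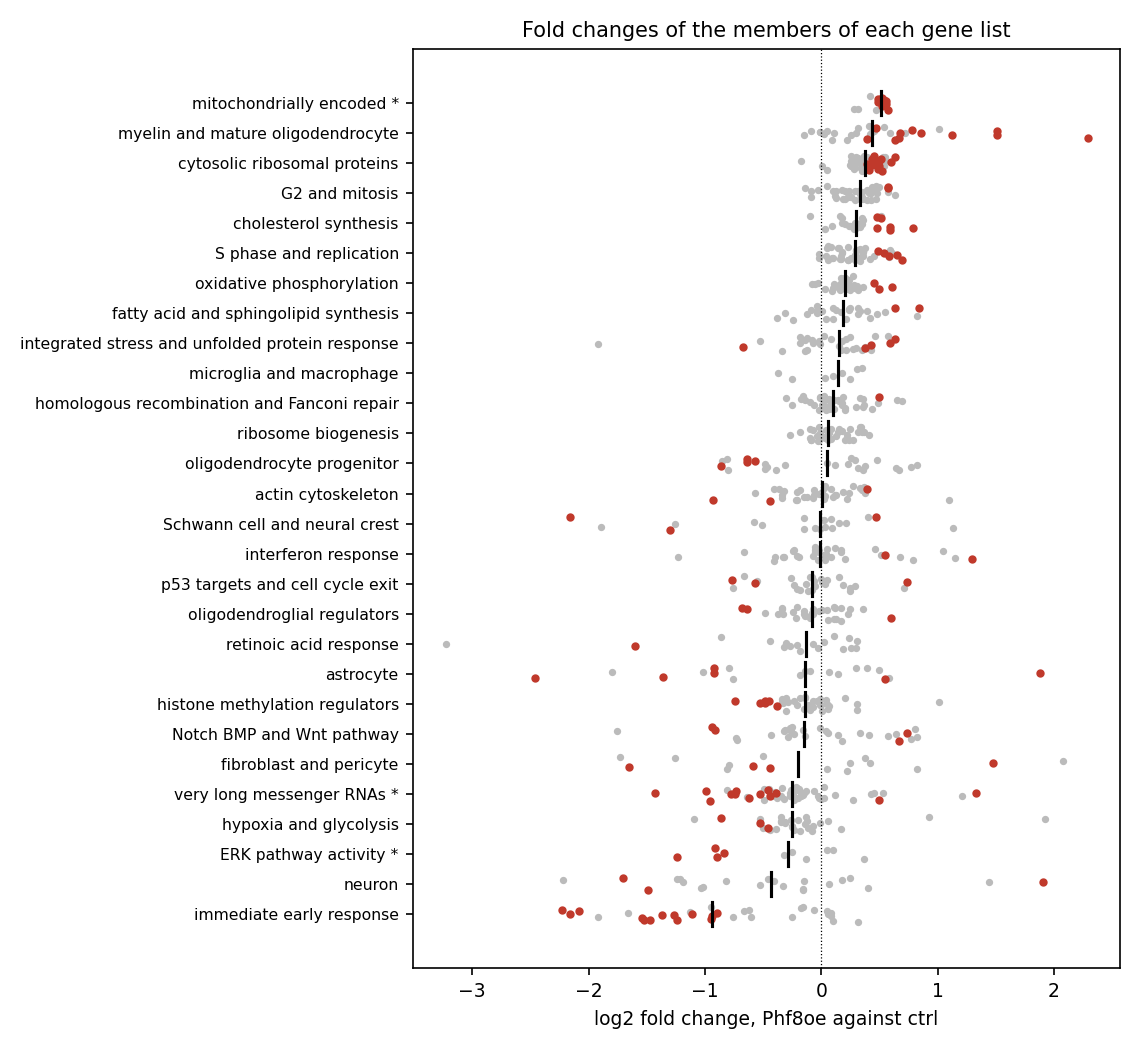
Log2 fold change (Phf8oe against ctrl) of each measured member of the 25 gene lists fixed beforehand and of 3 lists added later (asterisk); red points have a limma adjusted p under 0.05 and black bars are list medians. The immediate early response has the lowest median at -0.94, and the myelin list stands at 0.44.

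Over all 25 lists, 12 passed camera with the preset correlation, 8 higher and 4 lower. With an estimated correlation 0 passed, the smallest adjusted p being 0.552. That test rests on 2 residual degrees of freedom, so a pass was unlikely for any list. For the myelin list the estimated correlation was -0.02, yet the unadjusted camera p went from 6.48e-09 to 0.0221. The lost call of that list therefore cannot be put down to correlation between its genes. Over the 12 lists the estimate ranged from -0.02 to 0.77, the highest for G2 and mitosis. It was 0.66 for cytosolic ribosomal proteins and 0 for histone methylation regulators. Where the estimate was high, correlation between genes may account for the lost call as well. The preset 0.01 lies far below such estimates, so the preset p-values of those lists may be much too small. With limma's fry, which tests whether a list's genes move one way without comparing them with other genes, 1 list passed, that of myelin and the mature oligodendrocyte (adjusted p = 0.0423).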

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

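Counts of changed genes were recomputed under each alternative, and Phf8 under each but the test against a 1.5-fold change; pseudocounts 0.5 and 10, trimmed-mean scaling, crossed pairing and a constant variance prior were chosen after seeing the data. The 1098 calls kept their sign under every alternative fit of all genes, which was largely fixed in advance. Their groups do not overlap, so leaving out a library could not reverse them. Changes of block or variance prior leave the fold change as it was. The count lay between 1052 and 1244 with limma-voom, other scalings, filters and pseudocounts, and between 1018 and 1098 of the genes were shared. Without robust moderation 806 genes were called, 256 higher, and Phf8 passed (log2 fold change 1.89, adjusted p = 0.0194). With a variance prior that did not follow the level, limma called 0 genes (0 higher, 0 lower), with 3133 at an unadjusted p under 0.05 and 2.26 prior degrees of freedom. Voom, which models the trend by weights, called 1244. Against a 1.5-fold change 27 genes passed, 2 higher and 25 lower. Upper quartile scaling shifted the median of all genes to 0.047 and gave 608 higher and 589 lower, where the main split was 430 and 668.

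The deviations of same-numbered libraries correlated at -0.13, and only the numbers are shared. The replicate block gave 373 genes, 65 higher and 308 lower, and Phf8 passed (1.89, adjusted p = 0.0313). Crossed pairing gave 2354 genes, 1056 higher and 1298 lower. Leaving out 1 library gave 14 to 2103 genes, 1 to 905 higher and 13 to 1198 lower, and log2 fold changes of Phf8 from 1.42 to 2.35; the lone library was assumed to vary like the other group. Of 94 named genes past the threshold, 89 were lost without ctrl replicate 1, 71 without ctrl replicate 2, 5 without Phf8oe replicate 1 and 4 without Phf8oe replicate 2. The replicate block lost 47 of them, the fit without robust moderation 14 and the constant variance prior 94. Other fits lost 0 to 4. None reversed, which for most of these fits was fixed in advance as above. Each fit without a library has 1 residual degree of freedom, and the prior degrees of freedom were 5.89 and 6.05 without a ctrl library and 17.9 and 18.2 without a Phf8oe library. The adjusted p of Phf8 ranged from 2.98e-10 to 0.327.

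Lists past camera numbered 9 to 13 across fits, 0 with an estimated correlation and 1 with fry. Of the named genes, only 2 that never passed reversed: Ncl stood at 0.03 with upper quartile scaling, and ranged from -0.09 to 0.07 when 1 library was left out, and Cd68 stood at -0.01 with voom and ranged from -0.28 to 0.34. Except where stated, the cause was not tested. A planned DESeq2 Wald test and a planned legacy quasi-likelihood fit were not run, since they need raw counts. Phf8oe replicate 2 had the fewest reads, about 28400000, which limits the precision of low genes most there.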

Other observations

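The lists of mitochondrially encoded genes and of ERK pathway activity, the symbol families, and the tests of Gfap against its neighbours and against other astrocyte genes were chosen after the data were examined. Of 13 mitochondrially encoded genes 9 rose and none fell (median log2 fold change 0.51; camera adjusted p = 8.24e-08, and adjusted p = 0.167 with an estimated correlation in limma), among them Mt-co3, a cytochrome oxidase subunit, 1.46-fold. Of 10 genes that track ERK signalling 4 fell, Spry2, Phlda1, Dusp6 and Epha4, and none rose (camera adjusted p = 0.00314, and adjusted p = 0.137 with an estimated correlation). Spry2 and Dusp6 are also members of the immediate early list, so the 2 lists are not separate evidence. Of 80 families of genes sharing a symbol stem, 6 passed camera with the preset correlation and 0 with an estimated one. Among genes of mitochondrial ribosomal proteins, 4 of 42 Mrpl and 7 of 29 Mrps genes rose; Polr, Cox and Abhd also passed with the higher direction. Collagens passed with the lower (median -0.32; 5 of 27 fell and 2 rose). The adjusted p of each was 0.963 with an estimated correlation.

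Low genes outside the naming rule changed too. Hdac11, a histone deacetylase, rose from 3 and 6 normalized counts to 56 and 33, and its neighbour Fbln2 rose as well (log2 fold change 1.31). Brinp1 fell from 60 and 39 to 6 and 4, and Inhba, a subunit of activin, from 24 and 54 to 0 and 4. Phf8 was 2.67-fold over the ctrl mean in Phf8oe replicate 1 and 5.1-fold in replicate 2. Of the 1098 changed genes, 635 lay farther from ctrl in replicate 1 and 451 in replicate 2. The median size of their log2 change was close in both, 0.73 in replicate 1 and 0.68 in replicate 2. Genes are not independent, so 1 pair of libraries cannot show whether the response follows the level of Phf8.

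Median log2 fold changes were 0.38 for ribosomal protein genes, of which 17 of 65 rose, and -0.25 for very long messenger RNAs, of which 11 of 54 fell and 2 rose. Their difference in mean log2 level was 1.74 and 1.93 in ctrl and 2.37 and 2.52 in Phf8oe, a gap of 0.61 between groups against at most 0.18 within one; with 2 libraries per group and sets already seen to differ, a difference in preparation that fell with the group cannot be told apart from an effect of Phf8. The very long messenger RNAs had a median below all 10000 lists matched on level (middle 95% from -0.09 to 0.09), which ignore correlation between genes; camera gave adjusted p = 0.137 with an estimated correlation. A trend with transcript length, through RNA quality or fragment selection, may account for part of this, but lengths were not measured gene by gene. Whether such a trend is technical or a response to Phf8 stays open, since RNA quality values were not used here.

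Ccdc103 and FAM187A fell with their neighbour Gfap. Together they amounted to 1.74% and 0.788% of Gfap in the ctrl libraries and 0.687% and 0.462% in the Phf8oe libraries. The difference was 2.08-fold between groups against 2.21-fold between the ctrl libraries. Gfap itself stood at 79141 and 80736 in ctrl, which argues against a fixed share of its reads as the only source of their ctrl values. A share that varies, or Gfap reads beside a signal of their own, cannot be told apart from a change of their own. Neighbouring genes changed together more often than by chance elsewhere: leaving these genes out, 71 of 12068 neighbouring pairs were called in the same direction, against a mean of 40.9 in 10000 shuffles (permutation p = 0.0001, the smallest they can give) and 41.1 when shuffled among genes of like level. Examples are Fgf2, Nudt6 and Spry1, which all fell, and Dusp6 beside Kitlg. A shared regional response may underlie such pairs, but reads of overlapping genes (8 pairs) and transcription running on into a neighbour stay open.

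Gfap fell while myelin genes rose. Fewer astrocyte-like cells in the Phf8oe cultures would lower other abundant astrocyte genes about as much as Gfap if those genes came mainly from such cells. The log2 fold change of Gfap was -2.46. The 14 others with a mean of at least 100 had a median of -0.12 (SD 0.74), 8 lower and 6 higher, so they did not fall with Gfap as a set. Several of these genes, such as Clu, Vim and Slc1a3, are also expressed in the oligodendrocyte lineage. The values therefore cannot decide whether a small group of cells rich in Gfap was lost. No other explanation of this pattern was tested.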
